A study of Mus musculus with 12 samples.

How the data were processed

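RNA of ACSA-2-selected astrocytes was sequenced from both hemispheres of 6 mice, 12 libraries in 4 groups of 3, and the comparisons rest on the processed values that the authors deposited. Each library has its own table of 48709 genes with Ensembl identifiers and symbols, of which 48349 were found in the mm10 annotation. The deposited expression values are whole numbers and were taken as counts of reads per gene. The same tables hold deposited TPM, transcript levels scaled for length with the same sum in every library, and deposited RPKM, a constant multiple of the TPM within a library. The genome build is mm10 per the submitters' processing notes, and the aligner, the counting tool, the strand of counting and their settings are not given in the sources used here. Counts and TPM were not proportional for every gene. Of 13691 genes with at least 50 counts in a library, 64.8% had a ratio of counts to the reads implied by RPKM within 2% of the median. A further 507 genes had no counts but some TPM, 103 of them in all libraries, and such genes took 0.539 to 2.01% of TPM, so the counts seem to leave out reads that fit more than 1 gene. Within groups no 2 libraries were duplicates, the counts of each pair differing by 11.3 to 70.6 times counting noise (chi-squared per degree of freedom).

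The groups, comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10), which left 15571, libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted over all 12 libraries with 1 term per group, leaving 8 residual degrees of freedom. The 5 contrasts were ipsilateral against contralateral in mice labelled WT and in mice labelled KO, KO against WT on either side, and their interaction. P-values were adjusted by Benjamini-Hochberg over the genes tested and called at 0.05. Group levels are means ± SD of CPM over 3 libraries. The SE of a log2 fold change is its size divided by the square root of F, which is approximate. Intervals and floors (3 counts) cover counting error only. Totals were 11187723 to 15780600 counts per library.

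The 36 gene lists comprise 23 of functions or states, 12 of other cell types and 1 of sex-linked genes used to check the samples. Lists were tested by camera (limma 3.58.1) with a preset correlation of 0.01 on log2 CPM (prior count 2), adjusted over 170 tests, 34 lists in 5 contrasts. Of the lymphocyte list 0 of 10 genes had enough counts to be tested. Of the 170 tests 59 passed with the preset correlation, and 0 of these 59 passed with an estimated correlation, the smallest adjusted p being 0.408. Genes passing were counted with adjustment over all genes and over the list alone. Shared responses were counted against the number expected from independent calls.

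Genes were named by rule. These were the focus genes Wnt7a, Wnt7b, Axin2, Lef1, Ctnnb1, Vegfa, Gfap, Aqp4 and Lcn2, and per comparison the 10 largest rises and 10 largest falls among genes that passed, had a mean of at least 2 log2 CPM and stood apart between the groups, unnamed models and pseudogenes aside. Up to 4 members of each list with the smallest adjusted p were added, or 2 where none passed, and genes that a check of the samples needed. Where fewer than 10 genes passed, the 10 with the smallest p are given. Some genes that the rule picked, and some planned results, are not reported here.

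Alternatives were DESeq2 1.42.0 and limma-voom in the same design, RLE and upper-quartile scaling, no filter beyond 1 count, a stricter filter of 1 CPM in all libraries of a group, no robust estimation, and a fit of only the 2 groups compared. Further ones were the mouse as a block for comparisons within mice, camera with an estimated correlation, fry, and fits with each library and each mouse left out. Pairing was taken from the animal number. After removing group means, the 2 libraries of a mouse correlated across 12729 genes at 0.69, -0.02, 0.41, 0.39, 0.48 and 0.21 for mice 296, 297, 474, 295, 298 and 300. Libraries of different mice correlated at 0.49 (297 contralateral with 474 ipsilateral) and 0.29 (474 contralateral with 297 ipsilateral). The pairing of mouse 297 is thus not supported by these values. Deviations from a mean of 3 libraries sum to 0, so the mice of a group are not independent here. These values therefore do not show that the pairing is wrong either. Chosen after seeing the data were a limma-trend fit of log2(TPM + 1) for genes with a TPM of at least 1 in 3 libraries, and the mean log2 CPM of oligodendrocyte markers as a covariate. Planned variants of the pseudocount of normalised values did not apply, since counts are deposited. RPKM were not used here beyond the checks of units.

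The procedure was tested on simulated data made from gene means, library sizes and dispersions of the 12 libraries, with 100 genes changed 2-fold and 100 changed 4-fold in the KO ipsilateral group, among 15378 tested. Between KO and WT ipsilateral libraries edgeR found 54 and 93 of them with 3 false calls among 150 (2%). DESeq2 found 69 and 94 with 34 false calls among 197 (17.3%), limma-voom 49 and 92 with 5 among 146. The block fit was tried on another comparison, KO ipsilateral against KO contralateral, in the same data without simulated mouse effects, and found 40 and 93 with 7 among 140. camera found 10 of 10 changed lists and 0 of 200 unchanged ones with either correlation. The changed genes were drawn from those with a mean of at least 4 CPM. All members of a changed list were changed at least 2-fold in the same direction, so smaller or mixed shifts of a list were not tried. Genes were simulated independently of each other, so this cannot show how either correlation performs where genes of a list move together.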

Results

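RNA was sequenced from astrocytes of adult mouse brain that had been selected by ACSA-2, a surface antigen of astrocytes, 24 h after transient occlusion of the middle cerebral artery (tMCAO). In this stroke model the artery of 1 hemisphere is blocked for a time and then reopened. All mice carried Gfap-CreERT2, a Cre recombinase made in Gfap-expressing cells that acts after tamoxifen is given, and floxed alleles, which Cre deletes. The mice labelled WT (296, 297 and 474) received corn oil and the mice labelled KO (295, 298 and 300) received tamoxifen, so the drug and the deletion cannot be separated. The hemisphere of the occlusion (ipsilateral) and the opposite one (contralateral) of each mouse gave 1 library each, which makes 4 groups of 3 libraries. Total counts in the WT contralateral libraries of mice 296, 297 and 474 were 11935558, 12554526 and 12516804, and in the WT ipsilateral ones 12730472, 12458553 and 13448183. In the KO contralateral libraries of mice 295, 298 and 300 they were 11913464, 13462274 and 15780600, and in the KO ipsilateral ones 12930947, 14310388 and 11187723. Between 18292 and 19024 genes had at least 1 count per library, and 15571 genes were tested. Levels are given in CPM (read counts scaled to library size). Group names follow the labels, and every genotype direction is between libraries labelled KO and libraries labelled WT. The extent of the deletion is not reported here.

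The libraries also differed in ways that the group labels do not state. Mouse 296 had 8 and 4 counts of Xist with 2733 and 2917 counts of Y-linked genes, the pattern of a male, while the other 10 libraries had 9140 to 29592 Xist counts and 0 to 8 counts of Y-linked genes. Mitochondrial genes took 1.68% and 1.83% of counts in the KO ipsilateral libraries of mice 298 and 300, and 0.923 to 1.21% elsewhere. These shares leave out nearly all reads of some mitochondrial genes. mt-Co3 had at most 2 counts in a library, with group means of 6264 to 10715 TPM, and mt-Nd3 at most 4 counts. Markers of oligodendrocytes, a cell type the ACSA-2 selection should deplete, averaged 8.62 to 9.35 log2 CPM in WT contralateral libraries and 7.43 to 8.13 in KO contralateral ones. Genes of resting (homeostatic) astrocytes averaged 9.20 to 9.82 and 9.87 to 9.97 in these libraries. In WT ipsilateral libraries the oligodendrocyte average was 8.96 to 9.77 and the homeostatic one 8.27 to 8.49. RNA of other cells was thus present, and a change in a comparison below need not arise in astrocytes. Neutrophil markers averaged 3.31 and 4.09 log2 CPM in mouse 296 and at most 2.36 in the other mice. The microglial average was 3.73 in the KO ipsilateral library of mouse 300 and 6.64 and 6.09 in the other KO ipsilateral libraries. The first 2 principal components held 44.6% and 19.0% of the variance.

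**Figure D1:**
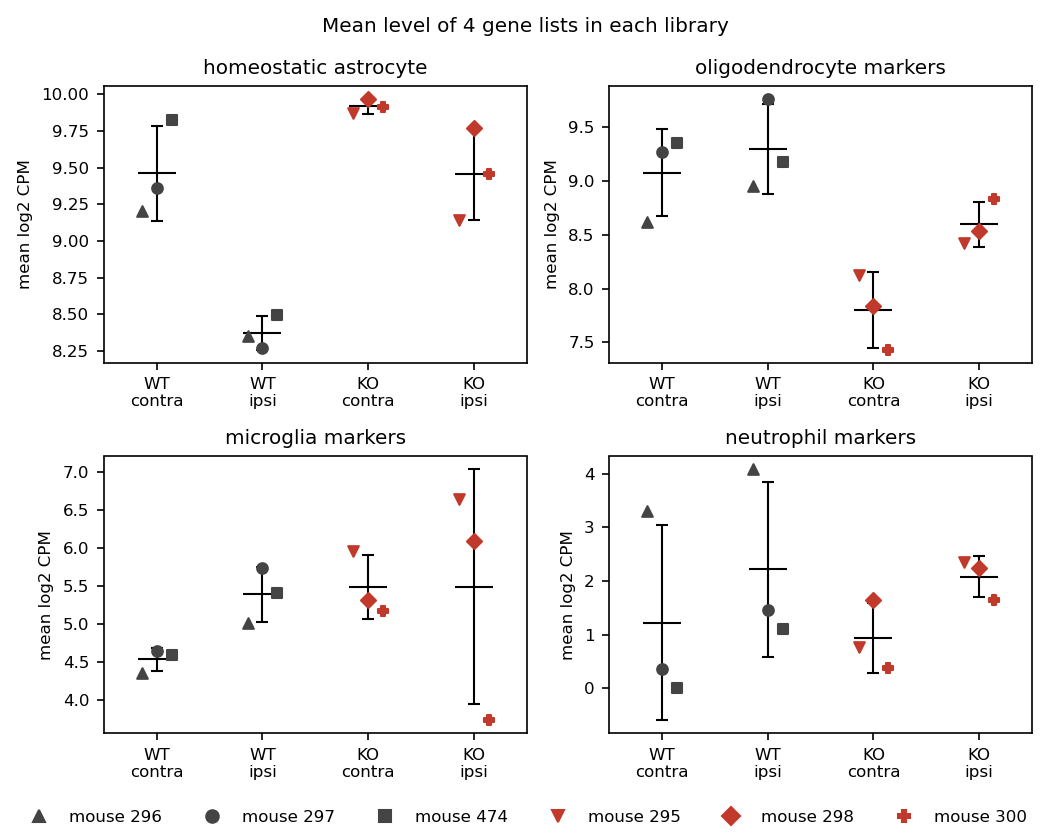
Mean log2 CPM of the homeostatic astrocyte, oligodendrocyte, microglia and neutrophil gene lists in each library, by group. The oligodendrocyte mean is 7.43 to 8.13 in KO contralateral libraries and 8.62 to 9.35 in WT contralateral ones, and the 2 highest neutrophil means are those of mouse 296.

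The comparison of ipsilateral with contralateral libraries of WT mice asks how the occlusion changed gene expression of the selected cells in mice given corn oil. Srxn1, which repairs oxidised peroxiredoxins, rose from 32.3 ± 4.10 to 677 ± 181 CPM (SD, n = 3 per group; log2 fold change 4.39 ± 0.43 SE), Hmox1 rose by 4.33 ± 0.72 and Txnrd1 by 2.51 ± 0.30. Osmr, the oncostatin M receptor, rose from 79.8 ± 39.2 to 623 ± 309 CPM (2.97 ± 0.51), and Cd44 rose by 2.41 ± 0.48. Fzd2, a Wnt receptor, fell from 174 ± 37.3 to 43.5 ± 6.51 CPM (-2.00 ± 0.20), and the Notch target Hes5 fell by 2.61 ± 0.55. In edgeR, 2982 of 15571 genes passed at an adjusted p of 0.05, 1497 higher and 1485 lower ipsilaterally, and 1236 of them changed more than 2-fold. The 3 libraries of each side stood fully apart in 5287 genes, 33.95% of those tested, where chance gives 10%. This 10%, here and below, assumes exchangeable libraries. Genes move together and the 2 sides share mice, so a share above it is not a test of the groups. Of the genes named for this comparison that passed, the groups overlapped in Hsd17b7, Hspa5, Slco1c1 and Srgn. The count was 1778 without the contralateral library of mouse 297, 1435 without the ipsilateral library of mouse 297, 1557 without the contralateral library of mouse 474, 659 without mouse 297 and 1212 without mouse 474. With the mouse as a block it was 4641, with only these 2 groups in the fit 1579 (996 higher and 583 lower), and with TPM 1570 were higher and 1086 lower.

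Among the genes with the largest rises in WT mice were Fga (7.42 ± 0.88), the interleukin 1 antagonist Il1rn (6.89 ± 0.66), the leukocyte adhesion receptors Selp (6.35 ± 0.82) and Sele (5.99 ± 0.71), Il11 (6.07 ± 1.12), Gdf15 (5.64 ± 1.16) and Il6 (5.32 ± 1.14). Over the contralateral libraries Fga had 4 counts, Il1rn 9 and Selp 7, and the ratios had 95% counting intervals of 70.4 to 666, 64.4 to 269 and 41.0 to 212. The counts held a share of 0.56 of the Il1rn reads that the RPKM values imply, so its level is less certain. Other shares under 0.6 among genes of this text were 0.45 for Cbs, 0.47 for Serpine2, 0.48 for Txnrd1, 0.49 for Hbegf, 0.50 for Ntsr2, 0.54 for Iigp1, Mmp14 and Tgfb1, and 0.597 for Slc12a2. Those of Gdf10, Ly86 and Tubb3, also under 0.6, are given beside these genes. Of 27 cytokine and NF-kB genes 23 rose, among them Ccl2 (2.97 ± 0.42), Cxcl2 (2.79 ± 0.44) and Cxcl16 (2.63 ± 0.40). The list's median was 2.47 with 25 of 27 members higher (camera adjusted p = 2.64e-12, 0.408 with an estimated correlation), and adjusted over the list alone 23 rose and 1 fell. Markers of monocytes and macrophages (median 1.28, camera adjusted p = 0.000589, 0.408 with an estimated correlation) and microglia (median 1.02, camera adjusted p = 0.0331, 0.853 with an estimated correlation) moved in the same direction. Of 25 interferon response genes 20 rose, and 21 adjusted over the list alone, among them Ifit3 (2.25 ± 0.35), Usp18 (2.06 ± 0.27) and Irf7 (2.03 ± 0.29). Interferon response genes had a median of 1.01, with 25 of 25 higher (camera adjusted p = 1.9e-11, 0.408 with an estimated correlation). The A2 list, reactive genes described after ischaemia, had 10 of 12 members rising, and 11 adjusted over the list alone, such as Ptx3 (4.15 ± 0.46), Ptgs2 (3.22 ± 0.38) and Cd14 (2.78 ± 0.46). Their median was 2.60 (camera adjusted p = 1.5e-08, 0.408 with an estimated correlation). Of the A1 list, described after inflammation, 4 of 11 rose on either adjustment, including Iigp1 (1.99 ± 0.33) and Gbp2 (1.65 ± 0.40). A1 genes had a median of 0.44 (camera adjusted p = 0.0333, 0.561 with an estimated correlation). That call was lost without mouse 296 (0.0944), its contralateral (0.0734) or ipsilateral library (0.0840), or the contralateral library of mouse 474 (0.0517). Of 13 pan-reactive genes 5 rose on either adjustment. Pan-reactive genes had a median of 0.83, with 13 of 13 higher (camera adjusted p = 0.000145, 0.524 with an estimated correlation). Gfap, the intermediate filament used to mark reactive astrocytes, did not pass (1895 ± 370 against 1197 ± 178 CPM, 0.66 ± 0.35; edgeR adjusted p = 0.207), except with the mouse as a block (0.0337). Lcn2 did not pass either (1.55 ± 1.01; edgeR adjusted p = 0.304), and it stood at 312 CPM in the contralateral library of mouse 296 and at 29.6 and 9.26 in the other contralateral libraries. It passed with the block (0.0117), without mouse 296 (0.0135) and without its contralateral library (0.00765).

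Of 21 protease and matrix genes 9 rose and 3 fell (10 and 5 adjusted over the list alone), with Plau (2.59 ± 0.33) and Mmp3 (5.10 ± 0.89) among the rises and a list median of 1.34 (camera adjusted p = 0.0072, 0.423 with an estimated correlation). Mmp12 had 2 counts over the contralateral libraries and 279 over the ipsilateral ones, a ratio of 129 with a 95% counting interval of 35.3 to 1067. Of 22 chaperone and stress response genes 8 rose (12 rose and 1 fell adjusted over the list alone), among them Asns (2.84 ± 0.49), Hspa5 (0.94 ± 0.25) and Xbp1 (0.63 ± 0.16). These chaperone and stress genes had a median of 0.66 (camera adjusted p = 0.000214, 0.554 with an estimated correlation). The antioxidant list had 5 rises and 1 fall, Gstm1 (-1.06 ± 0.18), of 19 on either adjustment. Their median was 0.26 (camera adjusted p = 0.0453, 0.605 with an estimated correlation). It did not pass without mouse 297 (0.181), its contralateral (0.0993) or ipsilateral library (0.0846), the contralateral library of mouse 296 (0.0659) or the ipsilateral library of mouse 474 (0.0852). Of 17 trophic factors 7 rose, such as Vgf (4.49 ± 0.85) and Tgfa (1.30 ± 0.18), and Ptn (-1.31 ± 0.21) and Mdk (-0.93 ± 0.15) fell (8 and 3 adjusted over the list alone; median 1.20, camera adjusted p = 0.0357, 0.545 with an estimated correlation). Trophic factors did not pass with the mouse as a block (0.0581) and without the contralateral libraries of mouse 297 (0.0594) or 474 (0.0607) or the ipsilateral library of mouse 296 (0.0661).

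Genes of resting astrocytes fell in WT mice after the occlusion. Of 24 homeostatic genes 20 fell and 4 did not pass, with all 24 lower adjusted over the list alone and a median of -1.06 (camera adjusted p = 8.93e-12, 0.416 with an estimated correlation). The neurotensin receptor Ntsr2 fell by 1.81 ± 0.28, the growth factor receptor Fgfr3 from 1855 ± 281 to 699 ± 211 CPM (-1.41 ± 0.23), the sulphur amino acid enzyme Cbs by 1.40 ± 0.17 and the glypican Gpc5 by 1.20 ± 0.19. Of 14 endfoot genes 9 fell (11 adjusted over the list alone), including the gap junction gene Gjb6 (-1.23 ± 0.28), Hepacam (-0.71 ± 0.14) and Mlc1 (-0.60 ± 0.15). Endfoot genes had a median of -0.60, with 14 of 14 lower (camera adjusted p = 1.84e-05, 0.408 with an estimated correlation). The water channel Aqp4 did not pass (-0.45 ± 0.30; edgeR adjusted p = 0.312), except with the mouse as a block (0.0449). The largest falls included Hes5, Kcnip2 (-2.38 ± 0.37), Gdf10 (-2.37 ± 0.26, with a share of 0.48 of its reads in the counts), Btbd17 (-2.05 ± 0.41), Fzd2, Kirrel2 (-2.00 ± 0.27), Fzd10 (-1.91 ± 0.42) and Cyp4f15 (-1.90 ± 0.30).

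Wnt pathway and vessel genes were measured because the study's title names Wnt/β-catenin signalling and angiogenesis. In WT mice Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783, mm10), a β-catenin target, fell from 59.96 ± 3.89 to 27.8 ± 5.36 CPM (-1.11 ± 0.14; edgeR adjusted p = 0.00105). The ligand gene Wnt7b (ENSMUSG00000022382, chromosome 15, 85535437 to 85582473) fell from 112 ± 34.1 to 58.7 ± 12.9 (-0.93 ± 0.20; edgeR adjusted p = 0.00928). Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369) fell from 346 ± 134 to 142 ± 29.6 (-1.29 ± 0.25; edgeR adjusted p = 0.00559). The 3 libraries of each side were apart in each of these genes. The Wnt7b call was lost without mouse 297 (edgeR adjusted p = 0.0513). An annotated gene overlaps Wnt7b and another overlaps Axin2, and the strand of counting is not stated. Wnt7a did not pass (-1.57 ± 0.56; edgeR adjusted p = 0.0705), its contralateral libraries standing at 11.2, 35.2 and 88.7 CPM. It passed with the block (0.00735), with DESeq2 (0.0179), with the oligodendrocyte covariate (0.0484), without mouse 296 (0.0131) and without its contralateral library (0.00627). With a library or mouse left out the Wnt7a value ranged from -2.03 to -0.58. Without the contralateral library of mouse 474 its edgeR adjusted p was 0.447. Of 16 Wnt ligand and secretion genes 3 fell on either adjustment, Wnt7b, the acyltransferase gene Porcn and Wnt5a (-0.78 ± 0.23). Wnt ligand and secretion genes had a median of -0.64, with 12 of 16 lower (camera adjusted p = 0.0364, 0.408 with an estimated correlation). That call was lost without the contralateral libraries of mouse 296 (0.0641) or 297 (0.0536), the ipsilateral library of mouse 297 (0.12) or mouse 297 (0.169). Of 35 receptor and transduction genes 10 fell (12 adjusted over the list alone), including Fzd2, Reck (-0.92 ± 0.19) and Tcf7l2 (-0.71 ± 0.15). The list did not pass (median -0.10, camera adjusted p = 0.073, and 0.0430 to 0.0476 without mouse 474, its contralateral library or the ipsilateral library of mouse 296). It holds receptors together with the complex that degrades β-catenin, so here and below its median gives no direction for Wnt signalling. Among 16 Wnt target genes Axin2 and Notum (-1.30 ± 0.28) fell while Ccnd1 (1.56 ± 0.28) and Myc (1.43 ± 0.37) rose (2 rises and 3 falls adjusted over the list alone; median -0.17, camera adjusted p = 0.629). Of 13 Wnt antagonists Sfrp5 (-1.52 ± 0.32), Dkk3 (-0.93 ± 0.11) and Dact3 (-0.81 ± 0.23) fell (4 falls adjusted over the list alone; median -0.42, camera adjusted p = 0.115, and 0.0463 without the ipsilateral library of mouse 296). Of 22 angiogenic factors 4 rose, including Thbs1 (2.56 ± 0.52) and Tgfb1 (0.73 ± 0.20), and Vegfa and Vegfb (-0.96 ± 0.24) fell (5 and 2 adjusted over the list alone; median 0.02, camera adjusted p = 0.85). This list holds secreted regulators of vessel growth without parting promoters from inhibitors. Here and below, its median therefore gives no direction for vessel growth.

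**Figure D2:**
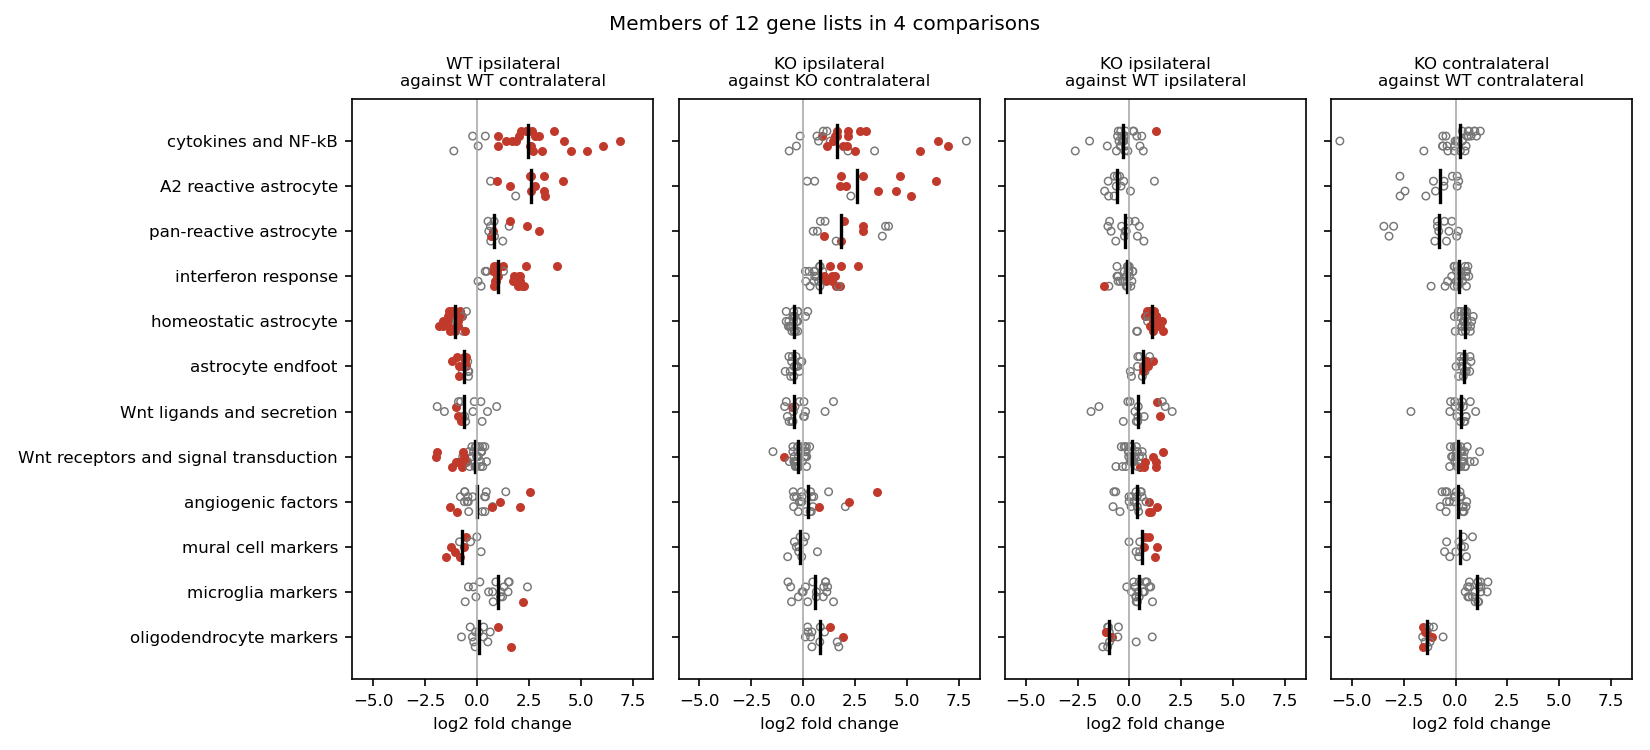
Log2 fold changes of the members of 12 gene lists in the 4 comparisons between groups, with members past an edgeR adjusted p of 0.05 filled in red and list medians as black bars. The homeostatic astrocyte median is -1.06 in WT ipsilateral against contralateral and 1.11 in KO against WT ipsilateral libraries.

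The same comparison within mice labelled KO asks how the occlusion changed the selected cells of mice given tamoxifen. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912) rose from 883 ± 468 to 3075 ± 1096 CPM (1.80 ± 0.36; n = 3 per group; edgeR adjusted p = 0.0188), all ipsilateral libraries lying above all contralateral ones, and this call held in 4 of 9 fits with a library or mouse left out. Ptx3, a pentraxin of the A2 list, rose by 6.42 ± 0.51, Srxn1 by 4.01 ± 0.42, Hmox1 by 4.17 ± 0.71, the thrombospondins Thbs1 by 3.55 ± 0.54 and Thbs4 by 2.20 ± 0.33, Osmr by 2.90 ± 0.51 and Cd44 by 2.90 ± 0.49. Klk9 had no counts contralaterally and 406 ipsilaterally, at least 148-fold higher against a floor of 3 counts over the group. Fosl1 rose from 5 to 1546 counts, and Gldn had a ratio of 139 (95% counting interval 47.2 to 677, from 3 counts contralaterally). In edgeR 979 genes passed, 848 higher and 131 lower ipsilaterally, 492 of them by more than 2-fold, and the groups stood apart in 6045 genes, 38.8% against 10% by chance. The count rested on single libraries, being 171, 23 and 86 without the contralateral libraries of mice 295, 298 and 300, and 201, 2282 and 264 without their ipsilateral libraries. Without mice 295, 298 and 300 it was 2, 750 and 48, while the mouse as a block gave 2498. The split between higher and lower genes also varied, being 1704 and 794 with the block, 1091 and 699 with only these 2 groups in the fit, and 370 and 182 with TPM. The oligodendrocyte marker mean as a covariate left 16 genes. It was 7.43 to 8.13 log2 CPM contralaterally and 8.43 to 8.83 ipsilaterally, so it cannot be separated from the side.

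In mice labelled KO 16 of 27 cytokine and NF-kB genes rose (21 adjusted over the list alone), such as Il11 (6.99 ± 1.15), Il1rn (6.49 ± 0.64), Lif and Cxcl16 (2.14 ± 0.38). Cytokine genes had a median of 1.62, with 24 of 27 higher (camera adjusted p = 2.31e-10, 0.408 with an estimated correlation). Monocyte and macrophage markers averaged 2.58 ± 0.43 log2 CPM contralaterally and 3.38 ± 0.23 ipsilaterally. The microglial averages were 5.48 ± 0.42 and 5.49 ± 1.54. Of 12 A2 genes 9 rose (11 adjusted over the list alone; median 2.60, camera adjusted p = 1.62e-09, 0.408 with an estimated correlation). Of 25 interferon response genes 10 rose (19 adjusted over the list alone), including Isg15 (1.79 ± 0.31) and Ifit3 (1.58 ± 0.34; median 0.81, camera adjusted p = 1.84e-09, 0.408 with an estimated correlation). Of 13 pan-reactive genes 5 rose (12 adjusted over the list alone), Osmr, Cd44, Aspg (1.98 ± 0.38), S1pr3 (1.02 ± 0.18) and Gfap. In these libraries pan-reactive genes had a median of 1.80 (camera adjusted p = 8.22e-08, 0.408 with an estimated correlation). Chaperone genes (5 of 22 rose, 14 adjusted over the list alone; median 0.70, camera adjusted p = 3.34e-05, 0.524 with an estimated correlation) included Atf4 (0.99 ± 0.21) and Ddit3 (1.18 ± 0.29). Antioxidant genes (4 of 19 rose, 5 adjusted over the list alone; median 0.50, camera adjusted p = 0.00103, 0.491 with an estimated correlation) included Gclm (1.04 ± 0.24). Of 21 protease genes 9 rose (12 rose and 1 fell adjusted over the list alone; median 1.74, camera adjusted p = 0.000365, 0.408 with an estimated correlation). The A1 list had 3 of 11 rising (5 adjusted over the list alone; median 0.62, camera adjusted p = 0.0203, 0.545 with an estimated correlation) and did not pass without mouse 298 (0.0555), its contralateral library (0.0727) or the ipsilateral library of mouse 300 (0.0512). Trophic factors did not pass as a list (5 of 17 rose, 7 adjusted over the list alone; median 0.32, camera adjusted p = 0.0724), though Bdnf (2.16 ± 0.42) and Hbegf (1.52 ± 0.29) rose.

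In mice labelled KO 0 of 24 homeostatic genes passed in edgeR on either adjustment, with 8 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma-voom. Of these genes 22 of 24 were lower and the median was -0.46 (camera adjusted p = 5.42e-05, 0.576 with an estimated correlation). Of 14 endfoot genes 0 passed in edgeR over all genes (10 at an unadjusted p under 0.05, 4 called by DESeq2, 0 by limma-voom) and 4 fell adjusted over the list alone. All 14 were lower, with a median of -0.45 (camera adjusted p = 0.000165, 0.423 with an estimated correlation). Axin2 fell from 72.6 ± 2.12 to 45.5 ± 4.45 CPM (-0.67 ± 0.14; edgeR adjusted p = 0.021), a call that held in 1 of 9 fits with a library or mouse left out. Fzd2 fell by 0.92 ± 0.20 and Porcn by 0.55 ± 0.13. Wnt7b (0.02 ± 0.20; edgeR adjusted p = 0.959), Vegfa (-0.46 ± 0.24; edgeR adjusted p = 0.245), Lcn2 (3.97 ± 1.13; edgeR adjusted p = 0.0586) and Aqp4 (-0.06 ± 0.30; edgeR adjusted p = 0.911) did not pass. Of these Lcn2 passed with the mouse as a block (0.00946), with DESeq2 (0.00433) and with only the 2 groups in the fit (0.0172). Wnt receptors and transducers had 1 fall of 35 (3 adjusted over the list alone; median -0.25, camera adjusted p = 0.031, 0.433 with an estimated correlation), a call lost without the contralateral library of mouse 300 (0.0765) or the ipsilateral library of mouse 298 (0.0754). Wnt ligands (median -0.43, camera adjusted p = 0.171), Wnt targets (median -0.03 and mean 0.21, camera adjusted p = 0.997) and angiogenic factors (3 of 22 rose; median 0.23, camera adjusted p = 0.191) did not pass. The largest falls were Spdef (-5.10 ± 1.26; 10 counts ipsilaterally) and Sspo (-4.74 ± 1.19), then Wfdc2 (-1.94 ± 0.40), Fam184b (-1.43 ± 0.35) and Gdf10 (-1.42 ± 0.25).

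The responses to the occlusion in mice labelled WT and KO shared many genes. Of the genes that passed in edgeR, 659 were higher in both, where 81.5 would be shared by chance, 112 were lower in both (12.5 by chance), and 0 went opposite ways. The 771 shared genes made up 77.7% of the rises and 85.5% of the falls called in mice labelled KO. Across all tested genes the fold changes correlated (Pearson r 0.794, Spearman rho 0.747; genes are not independent replicates), and over the 3190 genes called in either the slope of KO on WT was 0.752. With the mouse as a block 1961 genes were shared.

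The comparison of ipsilateral libraries labelled KO with those labelled WT asks how the deletion, with tamoxifen, changed the selected cells of the occluded hemisphere. Wnt7b stood at 161 ± 2.47 CPM in libraries labelled KO and 58.7 ± 12.9 in those labelled WT (1.46 ± 0.20; n = 3 per group; edgeR adjusted p = 0.00659). Vegfa, a growth factor for endothelium, stood at 356 ± 49.6 against 142 ± 29.6 CPM (1.33 ± 0.25; edgeR adjusted p = 0.0133). Axin2 stood at 45.5 ± 4.45 against 27.8 ± 5.36 (0.71 ± 0.14; edgeR adjusted p = 0.0167), and Aqp4 at 614 ± 140 against 282 ± 111 (1.12 ± 0.30; edgeR adjusted p = 0.0469). All 3 libraries labelled KO lay above all 3 labelled WT for each of these genes. With a library or mouse left out in turn Wnt7b passed in 11 of 12 fits, Vegfa in 6, Axin2 in 4 and Aqp4 in 2, and without mouse 297 their edgeR adjusted p-values were 0.0620, 0.0936, 0.114 and 0.216. Wnt7a (ENSMUSG00000030093, chromosome 6, 91363981 to 91411363) stood at 63.4 against 15.1 CPM and did not pass (2.06 ± 0.57; edgeR adjusted p = 0.0517). It passed with DESeq2 (0.00235), with only the 2 groups in the fit (0.0475), and in 3 of 12 fits with a library or mouse left out. Ctnnb1, which encodes β-catenin (-0.04 ± 0.14; edgeR adjusted p = 0.907), Lef1 (0.27 ± 0.19; edgeR adjusted p = 0.452), Gfap (0.70 ± 0.35; edgeR adjusted p = 0.282) and Lcn2 (-1.03; edgeR adjusted p = 0.599) did not pass either. In edgeR 983 genes passed, 675 higher and 308 lower in libraries labelled KO, 457 by more than 2-fold, and the groups stood apart in 3714 genes, 23.9% against 10% by chance. The count fell to 65 without the WT ipsilateral library of mouse 297 and to 0 without both libraries of mouse 297, where 2512 genes had an unadjusted p under 0.05 and the smallest edgeR adjusted p was 0.0596. It was 496 without the WT ipsilateral library of mouse 296, 518, 380 and 567 without the KO ipsilateral libraries of mice 295, 298 and 300, and 233, 107 and 222 without these mice. It was 967 without mouse 296, whose libraries had the male pattern. With only these ipsilateral groups in the fit the count was 196 (142 higher and 54 lower).

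**Figure D3:**
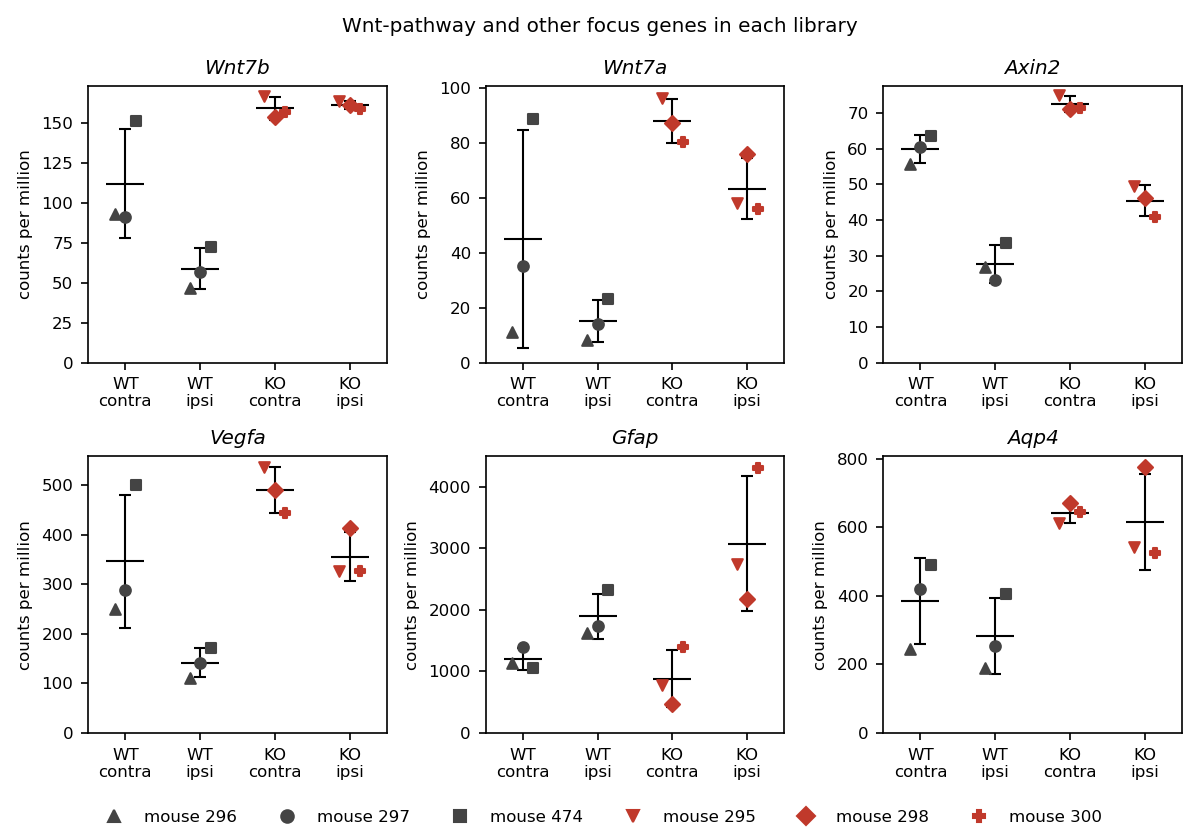
CPM of Wnt7b, Wnt7a, Axin2, Vegfa, Gfap and Aqp4 in each of the 12 libraries, with the mean and SD of each group of 3. Wnt7b averages 58.7 CPM in WT ipsilateral and 161 CPM in KO ipsilateral libraries, and Aqp4 282 and 614 CPM.

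Some other Wnt pathway genes were also higher in ipsilateral libraries labelled KO. Of 16 ligand and secretion genes Wnt7b and norrin (Ndp, 1.32 ± 0.35) were higher (4 higher and 1 lower adjusted over the list alone). The median of the ligand list was 0.41, with 12 of 16 higher (camera adjusted p = 0.0284, 0.408 with an estimated correlation). It did not pass without mouse 297 (0.2) or its WT ipsilateral library (0.188). Of 35 receptor and transduction genes 7 were higher (8 adjusted over the list alone), among them Lgr6 (1.30 ± 0.24), Fzd2 (1.16 ± 0.20), Tcf7l2 (0.73 ± 0.15) and the norrin co-receptor Tspan12 (0.71 ± 0.15). The receptor list had a median of 0.14, with 25 of 35 higher (camera adjusted p = 0.00923, 0.408 with an estimated correlation). Since it mixes receptors with genes that limit β-catenin, this gives no direction for Wnt signalling. Of 16 target genes Axin2, Tnfrsf19 (0.99 ± 0.26) and Znrf3 (0.54 ± 0.13) were higher (5 adjusted over the list alone), but the list did not pass (median 0.07, camera adjusted p = 0.213), except without mouse 296 (0.0285) or its WT ipsilateral library (0.0405). Of 13 antagonists Dkk3 was higher (1.07 ± 0.11; 3 adjusted over the list alone), and the list did not pass (median 0.32, camera adjusted p = 0.107), except without mouse 296 (0.0365) or its WT ipsilateral library (0.0241). Of 22 angiogenic factors Vegfa, Vegfb (1.06 ± 0.24), Angpt1 (0.94 ± 0.23) and Tgfb2 (0.93 ± 0.20) were higher (4 higher and 1 lower adjusted over the list alone). The angiogenic list had a median of 0.37, with 16 of 22 higher (camera adjusted p = 0.0349, 0.416 with an estimated correlation). That call was lost without the KO ipsilateral library of mouse 300 (0.156), the WT ipsilateral libraries of mouse 297 (0.0541) or 474 (0.105), or mice 297 (0.0618), 300 (0.142) or 474 (0.0647).

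Genes of resting astrocytes were higher in ipsilateral libraries labelled KO than in those labelled WT. Of 24 homeostatic genes 20 were higher (22 adjusted over the list alone). The homeostatic median was 1.11, with 24 of 24 higher (camera adjusted p = 2.99e-17, 0.408 with an estimated correlation). Aldoc, a glycolytic aldolase, stood at 2965 ± 736 against 1012 ± 122 CPM (1.55 ± 0.25), the mitochondrial glutamate carrier Slc25a18 at 375 ± 38.6 against 120 ± 22.0 (1.64 ± 0.23), and Acsbg1 (1.20 ± 0.20) and Cbs (1.09 ± 0.16) were higher as well. Mean homeostatic levels were 9.46 ± 0.32 and 8.37 ± 0.12 log2 CPM in contralateral and ipsilateral libraries labelled WT, and 9.92 ± 0.05 and 9.46 ± 0.31 in those labelled KO. Of 14 endfoot genes 5 were higher, Aqp4, Mlc1 (0.81 ± 0.15) and Dag1 (0.65 ± 0.14) among them (12 adjusted over the list alone). The endfoot median was 0.65, with 14 of 14 higher (camera adjusted p = 5.8e-07, 0.408 with an estimated correlation). Hes5 (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371) had the largest rise under the naming rule, 52.5 ± 10.8 against 8.46 ± 5.95 CPM (2.63 ± 0.55), followed by Prss56 (2.24 ± 0.56), Btbd17 (1.97 ± 0.41), Foxb1 (1.86 ± 0.41), Trib2 (1.73 ± 0.28) and Rlbp1 (1.68 ± 0.22). Of the 68 named genes that passed here 0 passed in edgeR without mouse 297 and 7 without its WT ipsilateral library.

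Fewer genes were lower than higher in ipsilateral libraries labelled KO, though TPM gave 338 lower and 347 higher, and some are markers of other cells. The choroid plexus transthyretin gene Ttr stood at 666 ± 340 against 3743 ± 1803 CPM (-2.49 ± 0.50), and Wfdc2 (-2.19 ± 0.40), Slc4a5 (-2.02 ± 0.47), Cldn1 (-2.73 ± 0.48), Fga (-3.41 ± 0.63) and Slc7a14 (-2.34 ± 0.45) were lower too. Of 14 ependymal and choroid plexus markers 2 were lower (3 adjusted over the list alone) and 9 lay above 0 (median 0.20 and mean -0.20, camera adjusted p = 0.851). Of 13 oligodendrocyte markers 3 were lower, with the myelin genes Mal (ENSMUSG00000027375, chromosome 2, 127633226 to 127656695; 849 ± 163 against 1826 ± 558 CPM, -1.10 ± 0.24) and Cnp (-0.83 ± 0.22) among them (9 adjusted over the list alone; median -0.97, camera adjusted p = 0.000145, 0.523 with an estimated correlation). Of 10 mural cell markers 5 were higher on either adjustment, such as Higd1b (1.35 ± 0.21), Vtn (1.25 ± 0.22), Notch3 (0.77 ± 0.17) and Rgs5 (0.71 ± 0.14; median 0.61, camera adjusted p = 0.000193, 0.452 with an estimated correlation). Cytokine genes did not pass as a list (median -0.29, camera adjusted p = 0.122), with Lif alone higher over all genes (1.26 ± 0.34) and 0 members adjusted over the list alone. Among 27 pH and ion transport genes the scaffold gene Slc9a3r1 (1.10 ± 0.16) and Car8 (1.43 ± 0.33) were higher, and 4 were lower, including Slc12a2 (-0.99 ± 0.18) and Slc8a3 (-1.63 ± 0.37; 4 higher and 8 lower adjusted over the list alone; median -0.04, camera adjusted p = 0.321). Of the trophic factors Ptn (1.20 ± 0.21) and Mdk (0.88 ± 0.15) were higher and Tgfa lower (-0.77 ± 0.18; 3 and 2 of 17 adjusted over the list alone; median -0.15, camera adjusted p = 0.85). Serpine2 (0.92 ± 0.22), Mmp14 (0.89 ± 0.16) and Timp4 (0.89 ± 0.21) were higher among 21 protease genes (3 on either adjustment; median 0.04 and mean -0.03, camera adjusted p = 0.98).

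The contralateral libraries labelled KO and WT were compared to ask how the selected cells of the hemisphere without occlusion differed. Myelin genes were lower in libraries labelled KO. Mag stood at 404 ± 151 against 1186 ± 122 CPM (-1.55 ± 0.29; n = 3 per group; edgeR adjusted p = 0.0231), Mal at 721 ± 115 against 1915 ± 28.4 (-1.41 ± 0.24) and Cnp at 787 ± 206 against 1758 ± 177 (-1.16 ± 0.23), with all libraries labelled KO below all labelled WT. Of 13 oligodendrocyte markers 5 were lower over all genes and 12 adjusted over the list alone. The oligodendrocyte median was -1.36 (camera adjusted p = 8.22e-11, 0.408 with an estimated correlation). The glucocorticoid-responsive kinase gene Sgk1 (202 ± 30.0 against 933 ± 431 CPM, -2.21 ± 0.42), Arrdc2 (-2.34 ± 0.46), Ttr (-2.36 ± 0.50), Spock1 (-2.53 ± 0.51), Snx22 (-2.44 ± 0.50) and Smco3 (-2.18 ± 0.35) had some of the largest falls, and so did Tubb3 (-2.35 ± 0.39, with a share of 0.18 of its reads in the counts). Of the transporters Slc12a2 (-1.04 ± 0.18), the carbonic anhydrase Car14 (-1.21 ± 0.18) and Slc4a2 (-0.70 ± 0.14) were lower. Few genes were higher, among them Grin2b (1.22 ± 0.26), Pcdh19 (0.92 ± 0.13), Marcks (0.88 ± 0.14) and Egfr (144 ± 7.89 against 86.7 ± 8.81 CPM, 0.73 ± 0.16). Wnt7b (0.51 ± 0.20; edgeR adjusted p = 0.275), Vegfa (0.50 ± 0.24; edgeR adjusted p = 0.378), Axin2 (0.28 ± 0.14; edgeR adjusted p = 0.399), Wnt7a (0.97 ± 0.54; edgeR adjusted p = 0.436), Aqp4 (0.74 ± 0.30; edgeR adjusted p = 0.285) and Gfap (-0.44 ± 0.35; edgeR adjusted p = 0.57) did not pass. Without mouse 474 Wnt7b (0.79; edgeR adjusted p = 0.0177), Vegfa (0.87; edgeR adjusted p = 0.0380) and Wnt7a (1.92; edgeR adjusted p = 0.0413) passed. Lcn2 (-3.46 ± 1.11; edgeR adjusted p = 0.18) passed with DESeq2 (0.0328) and without mouse 474 (0.0475). With a library or mouse left out its value ranged from -4.18 to -0.86. Without the WT contralateral library of mouse 296 its edgeR adjusted p was 0.822. In edgeR 233 genes passed, 13 higher and 220 lower, 169 by more than 2-fold, and the groups stood apart in 3808 genes, 24.5% against 10% by chance. Of the 220 lower genes 141 were also lower ipsilaterally, where 4.35 would be shared by chance, and 4 of the 13 higher genes were also higher (0.564 by chance). These chance figures assume independent calls, while both sides come from the same 6 mice. The count was 0 without the contralateral library of mouse 298 (1433 at an unadjusted p under 0.05) or 300 (1561), or without mouse 298 (1511), and 1 without mouse 300. It was 55 and 127 without the contralateral libraries of mice 297 and 295, and 69, 60, 391 and 333 without mice 297, 295, 474 and 296. With the oligodendrocyte marker mean as a covariate, chosen after the data had been seen, it was 0 (2413 at an unadjusted p under 0.05). That mean was 7.43 to 8.13 log2 CPM in libraries labelled KO and 8.62 to 9.35 in those labelled WT. The covariate therefore cannot be separated from the group, and this count does not show that oligodendrocyte content explains the differences.

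Some lists shifted on the contralateral side without any member passing in edgeR over all genes. Homeostatic genes had a median of 0.44 with 22 of 24 higher in libraries labelled KO and 0 passing on either adjustment (7 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom; camera adjusted p = 8.73e-07, 0.524 with an estimated correlation). Endfoot genes had a median of 0.39 with 14 of 14 higher and 1 higher adjusted over the list alone (8 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom; camera adjusted p = 3.34e-05, 0.408 with an estimated correlation). Wnt receptors and transducers had a median of 0.11 with 28 of 35 higher and 0 passing on either adjustment (5 at an unadjusted p under 0.05, 0 in DESeq2 and limma-voom; camera adjusted p = 0.00576, 0.408 with an estimated correlation). Wnt ligands (median 0.27, camera adjusted p = 0.235), Wnt targets (median 0.10 and mean -0.03, camera adjusted p = 0.641) and angiogenic factors (median 0.12, camera adjusted p = 0.379) did not pass. Pan-reactive genes had a median of -0.81 with 11 of 13 lower and 0 passing (4 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom; camera adjusted p = 0.0191, 0.688 with an estimated correlation), a call lost without mouse 296, 297 or 298 or their contralateral libraries (0.0741 to 0.197).

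The interaction asks whether the response to the occlusion differed between mice labelled KO and WT. In edgeR 0 of 15571 genes passed, the smallest adjusted p being 0.948, with 763 genes at an unadjusted p under 0.05. DESeq2 called 20 genes, all higher, and limma-voom called 0 (703 at an unadjusted p under 0.05). The focus genes did not pass, with differences of 0.95 ± 0.28 for Wnt7b, 0.82 ± 0.35 for Vegfa, 0.44 ± 0.20 for Axin2 and 1.14 ± 0.50 for Gfap (edgeR adjusted p = 0.948 for each, n = 3 per group). The genes with the smallest p-values were Lyve1 (-2.54 ± 0.43, unadjusted p = 7.7e-05 in edgeR), Fbxo2 (1.10 ± 0.20), Sec14l2 (0.99 ± 0.19), Dkk3 (0.80 ± 0.16), Neb (-2.32 ± 0.50), Scara3 (0.93 ± 0.20) and Ndufa4l2 (1.25 ± 0.29), each with an edgeR adjusted p of 0.948. A gene called within 1 genotype and not within the other is therefore not shown to respond differently. By camera with the preset correlation 10 lists differed. Homeostatic genes had a median difference of 0.69 with 24 of 24 above 0 (camera adjusted p = 9.18e-11, 0.433 with an estimated correlation), the fall after the occlusion being smaller in mice labelled KO, and 3 were called adjusted over the list alone. Cytokines differed by -0.43 (8 of 27 above 0; camera adjusted p = 0.000765, 0.491 with an estimated correlation), but not without mouse 297 (0.0749). Interferon response genes differed by -0.37 (4 of 25 above 0; camera adjusted p = 0.000402, 0.554 with an estimated correlation), but not without mouse 296 (0.186) or its ipsilateral library (0.114). Wnt ligands (median 0.38, camera adjusted p = 0.149), receptors (median 0.13, camera adjusted p = 0.73) and targets (median 0.27, camera adjusted p = 0.303) and angiogenic factors (median 0.13, camera adjusted p = 0.134) did not pass. The ligands passed without mouse 474 (0.00762) or its ipsilateral library (0.0349).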

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

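Of the tests in this part, the correlation among oligodendrocyte markers, the search for libraries with tamoxifen but no deletion, the medians of other cell types, the cytokine median and the look at genes with TPM but few counts were chosen after the result was seen, and the bound for the cytokine median was tightened after its first value. The tests without mouse 296, without mouse 297 and of other splits, and the interaction tests, were planned.

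By camera on the interaction, with the preset correlation but not with an estimated one, libraries labelled KO and WT differed in the response of 10 gene lists. The median differences in log2 fold change were 0.69 for homeostatic astrocyte genes, 0.36 for oxidative phosphorylation, 0.18 for cholesterol synthesis, -0.43 for cytokines and NF-kB and -0.37 for the interferon response. Among other cell types they were -0.47 for microglia, -0.76 for monocytes and macrophages, 0.46 for mural cells, 0.78 for neurons and 0.32 for oligodendrocytes. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.416. Leaving out a library or a mouse ended 7 of them. Microglia lost the call without the ipsilateral library of mouse 300 (adjusted p = 0.913) or mouse 300 (0.493), cytokines without mouse 297 (0.0749), and the interferon response without mouse 296 (0.186) or its ipsilateral library (0.114). Cholesterol synthesis lost it without mouse 296, 300 or 474, either library of mouse 296 or 300, or the ipsilateral library of mouse 298 (0.0531 to 0.90), and also with the mouse as a block (0.0514). Neurons lost it without mouse 297 or 300, either library of mouse 300, the contralateral library of mouse 296 or the ipsilateral library of mouse 297 (0.0754 to 0.578). Oligodendrocytes lost it without mouse 300 or 474, the contralateral libraries of mice 297 and 300 or the ipsilateral libraries of mice 296 and 474 (0.0749 to 0.30). Monocytes lost it without mouse 297, the contralateral libraries of mice 295 and 474 or the ipsilateral libraries of mice 297 and 298 (0.0602 to 0.170).

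The TPM values, which the comparisons did not use, also differed between libraries labelled KO and WT for a few genes. Of 21 genes with a mean TPM of at least 50 and too few counts to test, 3 had all libraries labelled KO above all labelled WT in both hemispheres. These were the transcription factor genes Pou3f3 (mean TPM 99.5 ipsilateral and 139 contralateral in KO, against 54.2 and 95.3 in WT) and Sox2 (189 and 261, against 102 and 150), and Fam181b (124 and 166, against 42.0 and 91.9). The difference was not tested, and both hemispheres come from the same mice. Homeostatic astrocyte genes were also higher in libraries labelled KO on both sides, so these genes need not be a separate finding.

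Oligodendrocyte markers were lower in contralateral libraries labelled KO, with a median of -1.36. The male-pattern mouse 296 was not the source, since without it the median was -1.51. Fewer oligodendrocytes, or less of their free RNA, among cells selected by ACSA-2 may explain the fall. Within groups the 13 markers, none of which is in another list, moved together with a mean correlation of 0.42, between the 0.2 and 0.5 set as bounds, which leaves this open. Tamoxifen, with or without the deletion, could also act on these cells, and 0 libraries came from mice given tamoxifen without the deletion, so drug and deletion cannot be told apart.

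Homeostatic astrocyte genes were higher in ipsilateral libraries labelled KO, with a median of 1.11. A lower share of all other cells in these libraries would lower all their markers, if expression within those cells did not differ. Mural cell markers, the highest of 7 lists with at least 10 measured genes, had a median of 0.61 (SE 0.13). With 5 of the 10 mural markers higher in edgeR, the markers of other cells did not all fall. Expression within mural cells was not measured apart from their number, so the test cannot decide on cell shares. The SE in this part is taken over the genes of a list, which are not replicates, and holds no spread between mice. Smaller lists, such as the neutrophil one, were not included. Oligodendrocyte markers, the only list of the 7 below 0, had a median of -0.97 (SE 0.19), so a lower share of oligodendrocytes is not excluded. Mouse 297 alone did not carry the difference, the median being 1.05 without it, although 0 genes then passed in edgeR (2512 at an unadjusted p under 0.05). A milder response to the occlusion in mice labelled KO may underlie it. The cytokine median was -0.29, in the direction this predicts, but its camera adjusted p was 0.122. In the interaction cytokines (-0.43) and interferon genes (-0.37) also lay in that direction, though neither call held with an estimated correlation. Microglia markers averaged 4.54 log2 CPM contralaterally and 5.39 ipsilaterally in WT, and 5.48 and 5.49 in KO. Monocyte and macrophage markers averaged 1.75 and 3.07 in WT, and 2.58 and 3.38 in KO. Both lists thus rose less on average in mice labelled KO, though the KO ipsilateral microglial averages ran from 3.73 to 6.64. The mean rises of the A2 and pan-reactive lists were not smaller in mice labelled KO. A2 genes averaged 3.62 log2 CPM contralaterally and 6.37 ipsilaterally in WT, and 2.96 and 5.88 in KO. Pan-reactive genes averaged 6.25 and 7.80 in WT, and 5.39 and 7.58 in KO. The WT contralateral libraries ran from 2.56 to 4.84 for A2 genes and from 5.46 to 7.17 for pan-reactive genes. With this spread the means of these lists cannot tell whether their rises differed. A milder response thus stays open, as does an effect of the deletion or of tamoxifen.

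Other splits of the 6 libraries of each comparison number 10 with the real one, too few for a share under 0.05. The real splits gave 2982, 979, 983 and 233 genes in the order of the report, and each was the only 1 of 10 to give as many, the highest others being 538, 0, 0 and 0. For the interaction the real split gave 0 genes and the highest other 0, so all 10 gave as many. In the comparisons within mice 4 splits part all 3 pairs, and the highest other of these gave 0 genes in either genotype.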

How the results depend on the processing

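The fit of log2(TPM + 1) and the oligodendrocyte covariate were chosen after seeing the data; all other alternatives were planned. Of 308 named gene results, RLE scaling, DESeq2 and non-robust estimation ended 0 calls, the stricter filter ended 2, upper-quartile scaling 7, limma-voom 26, no filter 31, TPM 50, only the 2 groups compared 83 of 298, the mouse as a block 3 of 199 (5 gained) and the covariate 121. These totals include focus genes that had not passed and so had no call to lose. Named genes that passed numbered 110, 67, 68 and 27 in the comparisons between groups, in the order of the report. No named gene that passed changed sign under any setting. Named genes and lists outside the focus and Wnt genes that did not pass were not rerun. Where no construction below explains a change, the cause was not tested.

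Genes called in WT mice after the occlusion numbered 1579 with only the 2 groups and 4641 with the mouse as a block (left-out libraries 659 to 3610). In mice labelled KO they numbered 2057 with DESeq2, 1790 with 2 groups, 2498 with the block, 552 with TPM and 16 with the covariate (2 to 2282). Between ipsilateral groups they numbered 1753 with DESeq2, 196 with 2 groups and 526 with the covariate (0 to 1351), and between contralateral groups 660 with DESeq2, 149 with TPM and 0 with the covariate (0 to 391). For the interaction DESeq2 called 20 genes, and edgeR 0 in every fit with libraries left out. DESeq2 was not run with libraries left out. Its false calls were 17.3% in the simulation of KO against WT ipsilaterally, and the interaction was not tested there. Shared responses numbered 1961 with the block, 1482 with DESeq2, 480 with TPM and 16 with the covariate. The covariate's values stood apart between the 2 groups of each comparison except WT ipsilateral against contralateral. There its effect cannot be separated from that of the group.

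Of 170 list tests 59 passed, 0 with an estimated correlation and 34 with fry (left-out libraries 53 to 68). Of 55 tests of other cell types 16 passed, 0 with an estimated correlation and 6 with fry (14 to 21). The block ended the calls for trophic factors in WT mice (0.0581) and cholesterol synthesis in the interaction (0.0514), and gained neutrophils in mice labelled KO (0.0475), and endfoot (0.0488) and endothelial lists (0.0485) in the interaction.

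Reversals were 38 in number, 3 of them of a called value. Those 3 were oxidative phosphorylation between contralateral groups (left-out range -0.20 to 0.047, 2 reversals) and microglia in the interaction (-1.27 to -0.049, by the test's direction). List values in this part are medians of differences in mean log2 CPM, which differ from the edgeR medians elsewhere, the microglial one being -0.72 here and -0.47 in edgeR. The others were of values that had not passed. Ctnnb1 was -0.076 with TPM in KO mice after the occlusion, -0.15 with the covariate between contralateral groups and 0.0065 with it in the interaction. Wnt7b in KO mice was -0.015 with upper-quartile scaling, -0.15 with TPM and -0.19 with the covariate. Lef1 between contralateral groups was -0.0025 with the stricter filter, -0.0029 with 2 groups and -0.16 with the covariate. With libraries left out the ranges in KO mice after the occlusion were -0.25 to 0.027 for Aqp4, -0.028 to 0.21 for Ctnnb1, -0.0041 to 0.058 for Wnt7b and -0.095 to 0.047 for Wnt targets. Between contralateral groups they were -0.022 to 0.12 for Ctnnb1, -0.10 to 0.15 for Lef1 and 0.025 to 0.32 for Wnt antagonists. Ctnnb1 ranged from -0.17 to 0.073 between ipsilateral groups, and in the interaction Lcn2 ranged from -0.17 to 3.15 and Wnt receptors from 0.0047 to 0.16. A median and the test's direction can differ in sign. In the simulation of KO against WT ipsilaterally 54 of 100 changes of 2-fold were found, so a change that did not pass is not shown to be absent.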

Other observations

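The comparisons in this part were planned, and only the choice of which to describe here was made after the results were seen.

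Markers of other cells also moved with the occlusion. In mice labelled WT 3 of 12 monocyte and macrophage markers rose on either adjustment, including Lyve1 (2.81 ± 0.32) and Chil3 (2.70 ± 0.65; median 1.28, camera adjusted p = 0.000589, 0.408 with an estimated correlation). Plac8, the other, had 3 contralateral and 25 ipsilateral counts, a ratio of 7.68 with a 95% counting interval of 2.34 to 39.7. Microglia markers had a median of 1.02 with 1 of 18, Ly86 (2.21 ± 0.63, with a share of 0.27 of its reads in the counts), rising in edgeR over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0331, 0.853 with an estimated correlation). That call was lost without mouse 296 (0.0694) or 297 (0.0914), the contralateral library of mouse 296 (0.12), or the ipsilateral libraries of mice 297 (0.0909) and 474 (0.0553). Of 10 mural cell markers 6 fell (7 adjusted over the list alone), such as Myh11 (-1.47 ± 0.33) and Higd1b (-1.25 ± 0.21; median -0.72, camera adjusted p = 0.00485, 0.524 with an estimated correlation). Ependymal and choroid plexus markers had a median of -0.68 (1 of 14 fell on either adjustment; camera adjusted p = 0.0039, 0.631 with an estimated correlation), but did not pass without mouse 297 (0.177). Oligodendrocyte markers Gjb1 (1.66 ± 0.48) and Opalin (1.02 ± 0.32) rose (0 adjusted over the list alone; median 0.10, camera adjusted p = 0.531), and oligodendrocyte precursor markers Cacng4 (-1.05 ± 0.28) and Cspg4 (-0.60 ± 0.18) fell (median -0.47, camera adjusted p = 0.139).

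In mice labelled KO oligodendrocyte markers had a median of 0.80 with 13 of 13 higher ipsilaterally and Mbp (1.94 ± 0.52) and Opalin (1.28 ± 0.33) rising (6 adjusted over the list alone; camera adjusted p = 0.00213, 0.545 with an estimated correlation). Mbp averaged 5729 ± 5688 CPM ipsilaterally and 1491 ± 147 contralaterally. Ependymal markers had a median of -0.73 with 0 of 14 passing in edgeR on either adjustment (9 at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom; camera adjusted p = 0.000337, 0.545 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.23 with 0 of 48 passing (7 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom; camera adjusted p = 0.00136, 0.819 with an estimated correlation), lost without the ipsilateral library of mouse 300 (0.265) or without mouse 300 (0.393). Neutrophil markers passed with the mouse as a block (0.0475) and not in the main test (median 1.25, camera adjusted p = 0.44).

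Between ipsilateral libraries labelled KO and WT, oxidative phosphorylation genes had a median of 0.26 with 47 of 48 higher and 0 passing in edgeR (10 at an unadjusted p under 0.05, 0 in DESeq2 and limma-voom; camera adjusted p = 0.00026, 0.777 with an estimated correlation), lost without the KO ipsilateral library of mouse 300 (0.187) or mouse 300 (0.203). This KO ipsilateral library had the highest shares of mitochondrial (1.83%) and ribosomal protein genes (2.41%) of all libraries. Cholesterol synthesis genes, of interest because tamoxifen binds sterol enzymes, had a median of 0.14 with Mvd (0.79 ± 0.19) and Nsdhl (0.65 ± 0.17) higher (4 adjusted over the list alone; camera adjusted p = 0.0437, 0.777 with an estimated correlation). That call was lost without mouse 296, 298, 300 or 474 or any of their ipsilateral libraries (0.0672 to 0.666). Immediate early genes had a median of -0.25 with 0 of 23 passing (4 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom; camera adjusted p = 0.00554, 0.739 with an estimated correlation), lost without mouse 295 (0.0559) or 296 (0.0791) or their ipsilateral libraries (0.0564 and 0.0840). Of the oestrogen receptor list 0 of 9 passed over all genes (3 at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom; median -0.09, camera adjusted p = 0.72). The neutrophil median was -0.88 while camera's direction was up (camera adjusted p = 0.997).

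On the contralateral side microglia markers had a median of 1.01 with 18 of 18 higher in libraries labelled KO and 0 passing in edgeR (4 at an unadjusted p under 0.05, 0 in DESeq2 and limma-voom; camera adjusted p = 0.000365, 0.687 with an estimated correlation). Monocyte and macrophage markers had a median of 1.25 with 10 of 12 higher, 0 passing over all genes (8 at an unadjusted p under 0.05, 3 in DESeq2, 0 in limma-voom) and 6 adjusted over the list alone (camera adjusted p = 0.000324, 0.408 with an estimated correlation). Immediate early genes had a median of -0.44 with 0 of 23 passing (6 at an unadjusted p under 0.05, 0 in DESeq2 and limma-voom; camera adjusted p = 0.00557, 0.739 with an estimated correlation), lost without mouse 296 (0.297) or its contralateral library (0.275). Oxidative phosphorylation genes had a median of -0.15 (camera adjusted p = 0.0189, 0.888 with an estimated correlation), and the median of differences in mean log2 CPM (-0.14) turned to 0.013 without mouse 474 and to 0.047 without its contralateral library.

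The remaining lists did not pass by camera in WT mice after the occlusion. The adjusted p was 0.887 for hypoxia and glycolysis (median -0.06; Ero1l 1.38 ± 0.22 and Slc16a3 1.17 ± 0.27 rose), 0.44 for proliferation (median -0.06 and mean 0.06; Pcna 0.87 ± 0.13 and Mcm5 1.14 ± 0.33 rose) and 0.833 for pH and ion transport (median 0.00 and mean -0.08; 5 of 27 fell and 1 rose). It was 0.73 for endothelial markers (median -0.06), 0.486 for neurons (median -0.45), 0.887 for fibroblasts (median 0.20, camera direction down), 0.851 for erythroid markers (median -0.03). For further lists it was 0.766 for cholesterol synthesis (median -0.08), 0.394 for immediate early genes (median 0.08), 0.0763 for oxidative phosphorylation (median -0.19), 0.303 for the oestrogen receptor list (median 0.40) and 0.441 for neutrophils (median 1.13).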
